A study of Canis lupus familiaris with 11 samples.

How the data were processed

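Total RNA from 11 samples of canine SVF was labelled with biotin, from 6 µg each, and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are on a log2 scale, as judged from their range (1.22 to 14.8 over 32391 features). Partek is the tool named, per the submitters' processing notes, without a version; the summarization and normalization methods are not given in the sources used here. Array medians lay between 5.14 and 5.31 in the 3 company arrays and between 6.76 and 6.85 in the 8 arrays of dogs 2 and 3, so the sets were taken to have been normalized separately. Tests and differences were therefore taken only within a set. In the company set 29.5% of features had one identical value on all 3 arrays, and in a simulated median polish of 20 probes per feature 54.4% did with 3 arrays and 0 with 8. Of the features, 16545 named 1 gene, 370 several and 15476 none in the platform annotation. Of the single-gene features 15820 were matched by gene identifier to the names of the UU_Cfam_GSD_1.0 assembly and 0 symbols differed. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene was represented by the feature with the highest mean over the 8 arrays among those naming that gene alone, which gave 15947 genes.

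Groups came from the sample titles. The titles name dogs 2 and 3, while their characteristics carry one and the same description of the animal. Nothing says that the 2 samples per dog and condition were separate preparations, so p-values measure only the spread between these samples, which may be technical. The 8 arrays were fitted as 4 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 4 residual degrees of freedom), without a filter, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The main contrast was the mean of both dogs' differences. Other contrasts were each dog's own difference, the difference between them, and dog 2 minus dog 3 without incubation. A set of 30 gene lists, written before the data were examined, was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation. Members were counted past adjusted p 0.05 over all features and adjusted over the list alone. For the companies, differences of at least 2-fold were counted, and each list's median was set against 10000 random lists matched on level, with the range from the 2.5 to the 97.5 percentile.

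On simulated data with the main design, the fit recovered 66.3% of changes of 1 log2 unit and 96.8% of changes of 2 units. This was over 32391 features, with 6.75% of calls false. The noise was normal, independent and drawn from the fit's own variance estimates, with 100 features changed by each size. These shares are therefore a check of the code and do not measure what the real arrays could detect. Camera made 0 calls in 20 runs of 30 unchanged lists drawn with independent noise and called a list moved by 0.5 in 20 of 20 runs over 15947 genes. Correlated genes were not simulated.

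Named genes followed a rule fixed before the data were examined. In the main comparison these were up to 12 genes in each direction past the threshold with both PRP arrays on the same side of both SVF arrays in each dog, and up to 3 members of each list with the smallest p. For the dogs they were the 6 genes with the smallest p in each direction, and for each company the 6 genes farthest above and below both others among features above the median level. List members came by the same rule. The platelet genes beside PPBP, IL1B, CCL7, CYP1A1, TUBB1 in company C and the unnamed feature were chosen outside it, IL1B, CCL7, CYP1A1, TUBB1 and the unnamed feature after their values were seen.

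Replicate numbers 1 and 2 recur in all groups. Deviations from the group means of arrays with the same number correlated at 0.230 within dog 2, 0.160 within dog 3 and between 0.165 and 0.399 across the dogs. They were highest across the dogs within a condition (0.362 for SVF and 0.399 for PRP). The numbers may thus mark a difference shared by both dogs and need not pair samples within a dog. A planned fit with the 4 same-numbered pairs as a replicate block is given where it ended a call. A fit with the number as a term was added after the data were seen. Alternatives covered a filter on dim features, array centring, repeated quantile normalization within each set and over all 11 arrays, the variance model, the terms in the model, averaging of features, other list tests and leaving out each array, where the array left alone in its group was assumed to vary like the other groups. The ratio of 3' to 5' control probe sets was planned as a check of RNA quality and was not analysed here, because control features could not be told from the others by their numbers.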

Results

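Gene expression was measured on 11 Affymetrix arrays in canine stromal vascular fraction (SVF), the mixed stromal, vascular and immune cell pellet that remains when adipose tissue is digested. For 2 dogs (dogs 2 and 3), visceral fat was digested by 1 company, and the cells were profiled either without incubation (SVF, 2 arrays per dog) or after treatment with light-activated platelet-rich plasma (PRP) and a 6 h incubation at 37 °C (2 arrays per dog). PRP and incubation always went together, so every difference below belongs to both. A further dog gave 3 portions of about 20 g of fat that were processed by companies A, B and C, frozen for about 1 month and thawed, with 1 array each. The array values are log2 expression levels for 32391 features, of which 16545 named a single gene. Precision is limited by the number of arrays, 2 per group in dogs 2 and 3 and 1 per company.

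The first question was which genes PRP with incubation changed in both dogs. The clearest change was in PPBP, which encodes a chemokine precursor stored in platelets. It rose by 2.71 ± 0.19 log2 units (SE), or 6.54-fold (limma, adjusted p = 0.0295). In dog 2 the level was 7.53 ± 0.30 in SVF and 10.79 ± 0.029 after PRP (SD, n = 2). In dog 3 it was 6.98 ± 0.46 and 9.14 ± 0.20 (SD, n = 2), and both PRP arrays lay above both SVF arrays in each dog. One unnamed feature (14308441), near the bottom of the scale, fell by 1.61, and it is mentioned because the count of 2 features rests on it. No other feature passed adjusted p 0.05 over all features. At an unadjusted p below 0.05 there were 3061 features, 930 higher and 2131 lower, where 1620 would be found by chance. This balance depended on scaling: the PRP arrays had lower medians (6.76 to 6.77) than the SVF arrays (6.80 to 6.85), and with each array centred on its median 1951 were higher and 1275 lower. With repeated quantile normalization 1332 were higher and 1706 lower, and over all 11 arrays 1373 and 1750. With the 4 same-numbered pairs as a replicate block no feature passed, and the adjusted p of PPBP was 0.189. The PPBP call was also lost in the additive model (adjusted p = 0.0653), with condition alone (0.345), with the dog as a random block (0.296) and with 1 mean per dog and condition (0.0750). Leaving out any 1 of the 8 arrays also ended the PPBP call, with adjusted p between 0.0619 and 0.302 and differences between 2.55 and 2.87.

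**Figure D1:**
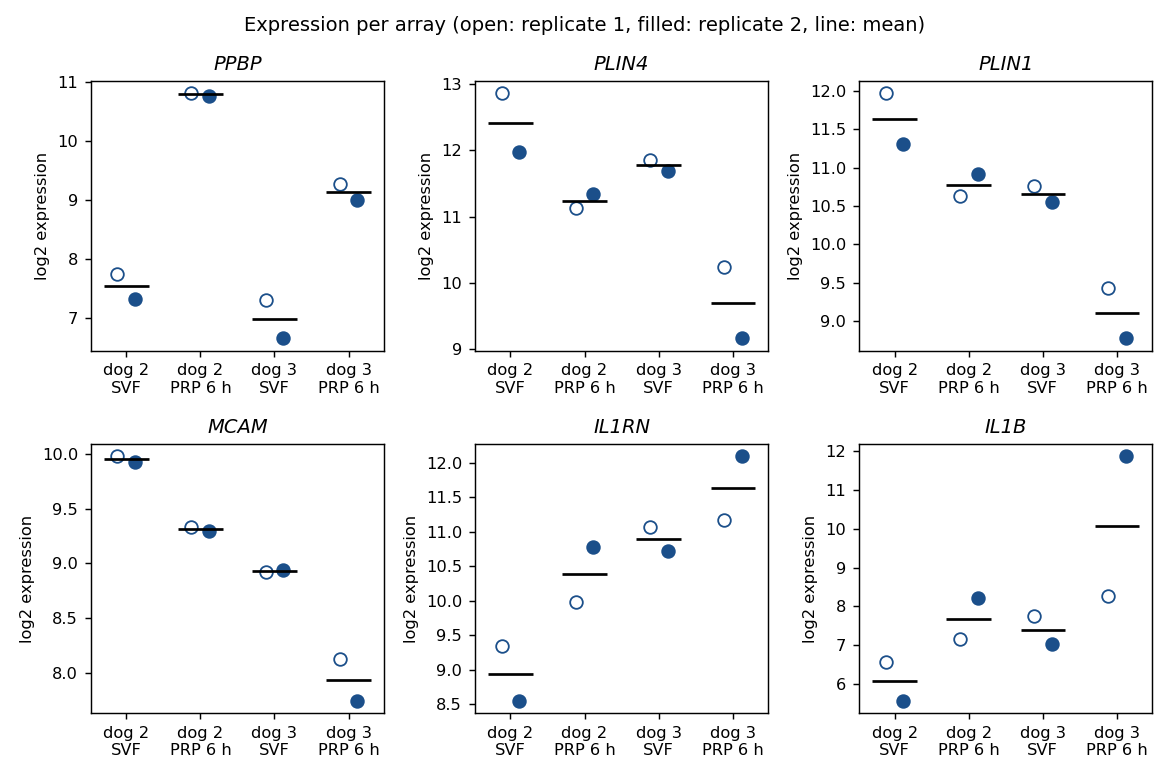
Log2 expression of 6 genes on each of the 8 arrays of dogs 2 and 3 (open circles, replicate 1; filled circles, replicate 2; lines, group means of n = 2; the vertical axes do not start at 0). PPBP averaged 10.79 and 9.14 after PRP against 7.53 and 6.98 in SVF, and IL1B, added after its values were seen, reached 11.88 on the dog 3 PRP replicate 2 array.

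Genes of mature fat cells were lower after PRP with incubation. Of 20 measured adipocyte markers, 19 had lower means, with a median difference of -0.52 (camera, adjusted p = 8.7e-13, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone, 10 members fell, while 0 passed over all genes. PLIN4 and PLIN1, which encode coats of the lipid droplet, fell by 1.62 ± 0.28 and 1.21 ± 0.21 (SE, limma, adjusted p = 0.00457 for each, adjusted over the list alone). LIPE, the hormone-sensitive lipase, fell by 0.74 ± 0.13 (SE) with the same list-adjusted p. Stromal and mesenchymal markers had a median of 0.031 over 21 members (camera, adjusted p = 0.904).

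Vascular wall genes were also lower. Of 16 pericyte and smooth muscle markers, 15 had lower means (median -0.27, camera, adjusted p = 3.0e-05, and adjusted p = 0.357 with an estimated correlation). MCAM, an adhesion molecule of perivascular cells, and ACTA2, smooth muscle actin, fell by 0.82 and 0.60 when adjusted over the list alone (limma, adjusted p = 0.00516 and adjusted p = 0.0393), and 0 members passed over all genes. Of 21 endothelial markers, 16 had lower means (median -0.29, camera, adjusted p = 0.00414, and adjusted p = 0.502 with an estimated correlation), and VWF, the von Willebrand factor, differed by -0.50 ± 0.17 (SE) without passing. The endothelial call was lost without dog 3 PRP replicate 2 (adjusted p = 0.0713, median -0.12), without both number 2 PRP arrays (0.288) and with condition alone (0.364), and the median was -0.17 without dog 2 PRP replicate 2 and -0.19 without dog 3 SVF replicate 2. Extracellular matrix genes had 21 of 28 members with lower means (median -0.16, adjusted p = 0.00600, and adjusted p = 0.504 with an estimated correlation). The 1 member of that list to pass adjusted over the list alone moved the other way: POSTN, a matricellular protein, rose by 0.89 ± 0.18 (SE, limma, adjusted p = 0.0347). The matrix call was lost without dog 2 SVF replicate 1 (adjusted p = 0.134).

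Of 25 measured inflammatory cytokines and chemokines, 24 had higher means (median 0.59, camera, adjusted p = 2.8e-08, and adjusted p = 0.357 with an estimated correlation). Of these, 10 had an unadjusted p below 0.05 and 0 passed adjusted over the list alone or over all genes. IL1RN, the interleukin-1 receptor antagonist, differed by 1.09 ± 0.30, CCL3 by 0.93 ± 0.29 and CCL5 by 0.77 ± 0.22 (SE). These differences were larger in the number 2 pairs: in dogs 2 and 3 IL1RN differed by 0.64 and 0.090 in the number 1 pairs against 2.24 and 1.38, CCL3 by 0.44 and 0.23 against 1.47 and 1.60, and CCL5 by 0.60 and 0.21 against 0.89 and 1.40. The dog 3 PRP arrays also stood farthest apart as replicates, with a root mean square difference over genes of 0.516 log2 units, against 0.347 to 0.365 in the other groups. T and NK cell markers had 21 of 25 members with higher means (median 0.34, adjusted p = 3.8e-06, and adjusted p = 0.407 with an estimated correlation). The median was 0.18 without dog 2 PRP replicate 1 and 0.17 without dog 3 SVF replicate 2. IL7R, the receptor for a T cell survival factor, differed by 1.55 ± 0.53 and CCR7, a lymph node homing receptor, by 1.21 ± 0.45 (SE). Both lay mainly in the number 2 pairs as well. IL7R differed by 0.42 (dog 2) and 0.095 (dog 3) in the number 1 pairs and by 3.22 and 2.49 in the number 2 pairs, and CCR7 by 0.41 and 0.19 against 1.27 and 2.97. Macrophage and monocyte markers had 18 of 22 members with higher means (median 0.29, adjusted p = 0.00161, and adjusted p = 0.531 with an estimated correlation). That call was lost without dog 2 PRP replicate 1, dog 2 SVF replicate 2 or dog 3 PRP replicate 1 (adjusted p = 0.231, 0.325 and 0.0554), with medians of 0.14 and 0.15 without the first 2. The median was 0.46 without dog 2 SVF replicate 1, 0.44 without dog 3 SVF replicate 1 and 0.19 without dog 3 SVF replicate 2.

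B and plasma cell markers were higher in 10 of 14 members (median 0.20, adjusted p = 0.0105, and adjusted p = 0.357 with an estimated correlation), a call lost without dog 3 SVF replicate 1 (adjusted p = 0.0540) or dog 3 PRP replicate 1 (0.0557, with a median of 0.13). Mast cell markers were higher in 7 of 9 (median 0.19, adjusted p = 0.0329, and adjusted p = 0.470 with an estimated correlation), and with the replicate block their adjusted p was 0.0738. The mast cell call was also lost without dog 2 SVF replicate 1 (adjusted p = 0.195), dog 2 PRP replicate 1 (0.231), dog 3 SVF replicate 1 (0.127) or dog 3 PRP replicate 1 (0.285). Platelet markers were higher in 9 of 13 (median 0.11, adjusted p = 0.0294, and adjusted p = 0.357 with an estimated correlation). PPBP was the 1 platelet marker to pass over all genes and adjusted over the list alone. The platelet list holds PPBP itself, and its mean was 0.32, well above its median. It was not tested without PPBP, so the call is not separate from the PPBP rise. With the replicate block the adjusted p of the platelet list was 0.0579. The platelet call was lost without dog 2 SVF replicate 1 (adjusted p = 0.0544, with a median of 0.17), dog 3 SVF replicate 1 (0.129) or dog 3 PRP replicate 1 (0.196, with a median of -0.028). The median was 0.035 without dog 2 PRP replicate 1, 0.047 without dog 2 SVF replicate 2 and 0.28 without dog 3 PRP replicate 2. It was also lost with a filter on dim features (adjusted p = 0.210, median -0.028), with repeated quantile normalization (0.0554 over the 8 arrays, 0.0536 over all 11) and with condition alone (0.160). The mast cell call was lost with the filter (0.0758), condition alone (0.409), 1 mean per dog and condition (0.0993) and the replicate number as a term (0.0520). Among the other platelet list members, CLEC1B, GP9, ITGA2B, ITGB3, NRGN and TUBB1 differed by between -0.089 and 0.31. Outside that range lay CCL5 (0.77), SELP (0.35) and SPARC (-0.18).

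All 14 measured genes of the NRF2 oxidative stress response had higher means (median 0.33, camera, adjusted p = 3.0e-05, and adjusted p = 0.470 with an estimated correlation), and SRXN1, an antioxidant repair enzyme and the member with the smallest p, differed by 0.93 ± 0.28 (SE). The median was 0.57 without dog 3 PRP replicate 1 and 0.17 without dog 3 PRP replicate 2. Without both number 2 PRP arrays, a setting chosen after the data were seen, the adjusted p of that list was 0.224. Cell cycle genes were higher in 20 of 26 (median 0.23, adjusted p = 0.00896, and adjusted p = 0.555 with an estimated correlation), oxidative phosphorylation genes in 16 of 18 (median 0.12, adjusted p = 0.0121, and adjusted p = 0.470 with an estimated correlation) and genes of the unfolded protein and integrated stress response in 18 of 21 (median 0.10, adjusted p = 0.0159, and adjusted p = 0.470 with an estimated correlation). Immediate early genes, which respond within minutes to handling and growth factors, were lower in 17 of 24 (median -0.23, adjusted p = 0.0154, and adjusted p = 0.531 with an estimated correlation). Repeated quantile normalization ended the calls for oxidative phosphorylation and the stress response (adjusted p = 0.0595 for each over the 8 arrays, 0.0536 for each over all 11), leaving 12 lists. Without both number 2 PRP arrays the stress response had an adjusted p of 0.519 and immediate early genes 0.889. Each of these 4 calls was lost when single arrays were left out. For the cell cycle these were dog 2 PRP replicate 1 (adjusted p = 0.394), dog 2 SVF replicate 2 (0.126), dog 3 PRP replicate 1 (0.461) and dog 3 SVF replicate 2 (0.0771), and the median itself went to -0.00093, 0.084, 0.066 and 0.035. For oxidative phosphorylation they were dog 2 SVF replicate 1 (0.0544), dog 3 PRP replicate 1 (0.105) and dog 3 SVF replicate 2 (0.0671, with a median of 0.064), and for the stress response dog 2 SVF replicate 1 (0.0544), dog 3 SVF replicate 1 (0.134) and dog 3 PRP replicate 2 (0.275, with a median of 0.050). Higher medians were found for oxidative phosphorylation without dog 3 SVF replicate 1 (0.23) and for the stress response without dog 3 PRP replicate 1 (0.20). For immediate early genes they were the replicate 2 arrays of dog 2 SVF (0.0573), dog 2 PRP (0.128, with a median of -0.14), dog 3 SVF (0.0671) and dog 3 PRP (0.310, with a median of -0.097).

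The other 15 lists did not pass. Their medians were 0.14 for neutrophil markers (adjusted p = 0.0807), 0.11 for erythroid markers, 0.095 for interferon response, 0.082 for angiogenic and growth factors, 0.071 for p53 targets and apoptosis, 0.046 for TGF-beta targets, 0.031 for the stromal list above and 0.0025 for hypoxia and glycolysis. Below zero lay matrix proteases and inhibitors (-0.0038), heat shock (-0.00955), cholesterol synthesis (-0.017), NF-kappaB targets (-0.027), cartilage and bone genes (-0.050), mesothelial markers (-0.075) and pluripotency genes (-0.14). Single members of 3 of these lists rose when adjusted over the list alone: SQLE, an enzyme of cholesterol synthesis, by 0.61 ± 0.12 (SE, limma, adjusted p = 0.0213), ALAS2, the erythroid enzyme that begins haem synthesis, by 0.53 ± 0.13 (adjusted p = 0.0448), and POSTN among TGF-beta targets (adjusted p = 0.0174). The median lay below zero but the mean above it for matrix proteases and inhibitors (mean 0.37), cholesterol synthesis (0.077), NF-kappaB targets (0.018) and cartilage and bone genes (0.0096), and camera's direction was up for the first 3 of these and down for the last. For heat shock the median and mean (-0.0035) were negative and camera's direction up, and for hypoxia and glycolysis the mean was -0.013 with a positive median and direction. In all, 15 of 30 lists passed with the preset correlation, 10 higher and 5 lower, and 0 with an estimated correlation.

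**Figure D2:**
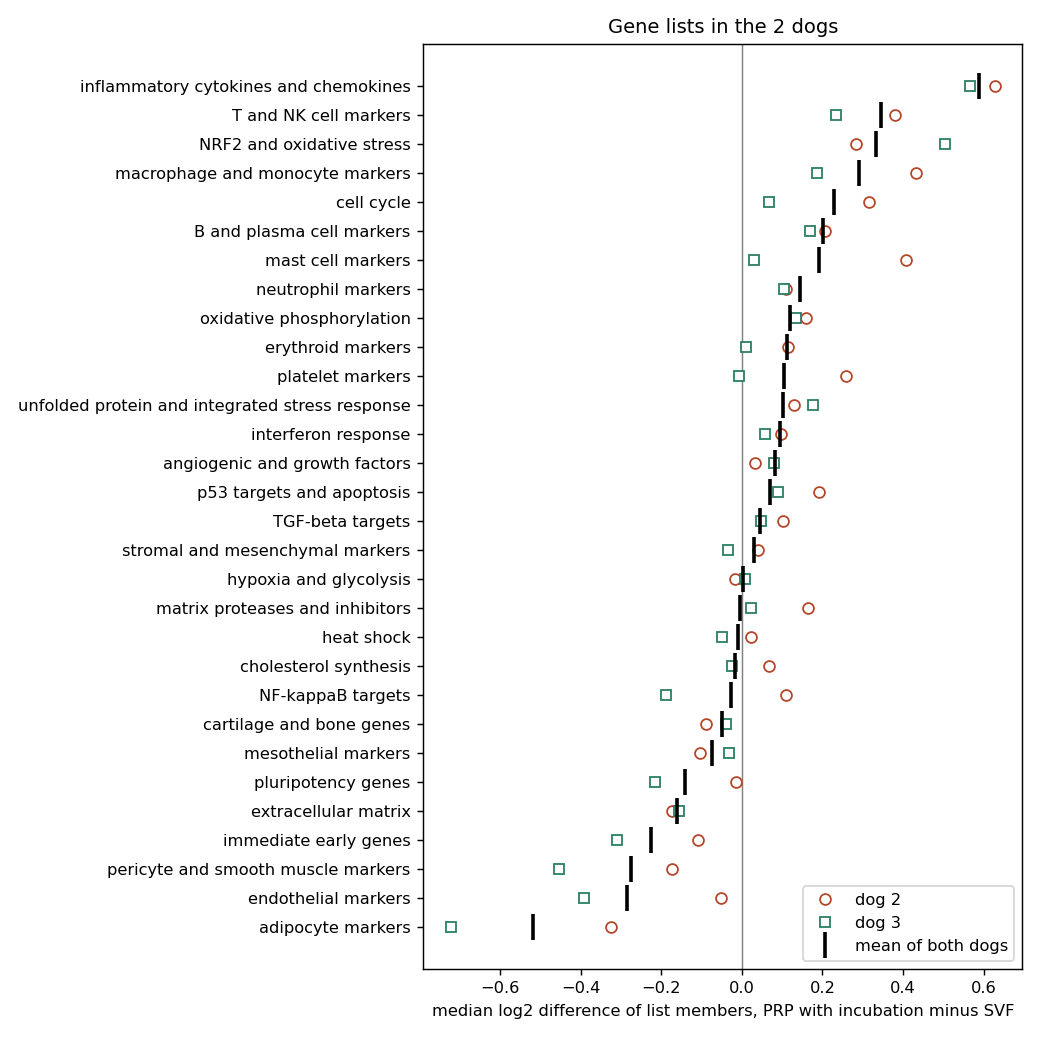
Median log2 difference, PRP with incubation minus SVF, of the members of each of 30 gene lists in dog 2 (circles), in dog 3 (squares) and for the mean of both dogs (ticks). Adipocyte markers lie lowest (median -0.52) and inflammatory cytokines and chemokines highest (0.59).

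The next question was whether the 2 dogs responded alike. Across 15947 genes the differences in dog 2 and dog 3 correlated with r = 0.613 and rho = 0.564, and 69.1% had the same sign. These are correlations across genes, which are not independent replicates. Arrays of the same number and condition also deviated together across the dogs (r = 0.362 for SVF and 0.399 for PRP). Effects shared in that way could raise the correlation without a shared response, and their part was not measured. Leaving out 1 array at a time gave r between 0.364 (without dog 2 PRP replicate 2) and 0.634. PLIN4 differed by -1.18 in dog 2 and -2.07 in dog 3. By their medians in dogs 2 and 3, some of the lists called above moved mainly in 1 dog. These were mast cell (0.41 and 0.029), platelet (0.26 and -0.0083), endothelial (-0.051 and -0.39) and cell cycle genes (0.31 and 0.067). Of all called lists, only that of platelet markers had medians of opposite sign in the dogs. Within dog 2 alone 0 features passed in limma (1423 at an unadjusted p below 0.05), within dog 3 alone 0 (1975), and the test of the difference between the dogs' effects gave 0 (619). Against the 1620 features that chance would give, the dog 2 and interaction counts are no larger.

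**Figure D3:**
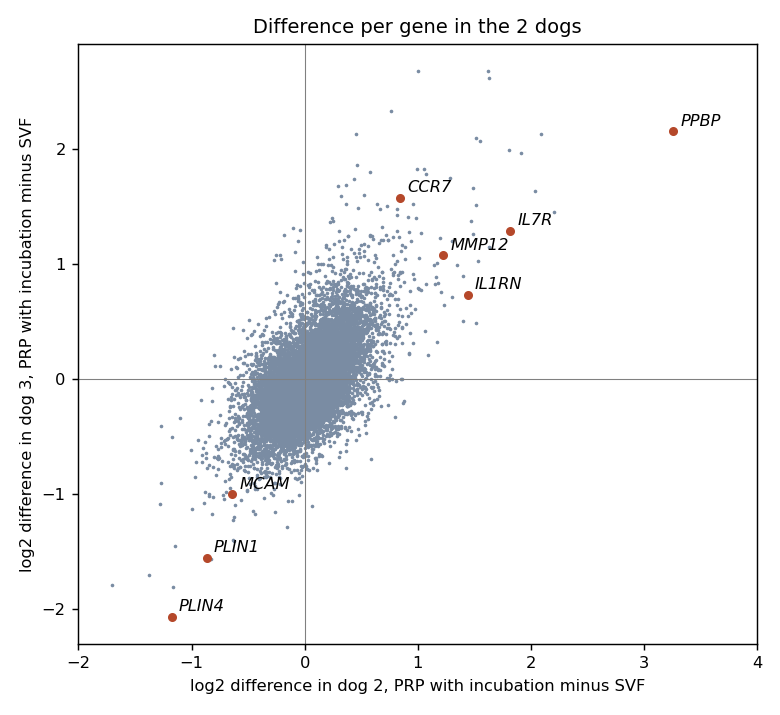
Log2 difference, PRP with incubation minus SVF, in dog 2 (horizontal) and dog 3 (vertical), each point 1 of 15947 genes, with 8 named genes in red. PPBP lies farthest to the right, at 3.26 in dog 2 and 2.16 in dog 3.

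The untreated cells of the 2 dogs were then set side by side, to size the difference between them. Each dog's cells came from its own fat, so the animal cannot be told apart from its tissue and preparation. SFRP4, a secreted inhibitor of Wnt signalling, was 27.6-fold higher in dog 3, at 11.91 ± 0.12 against 7.12 ± 0.022 in dog 2 (SD, n = 2, limma, adjusted p = 0.000367). PI3, the protease inhibitor elafin, was 7.21-fold higher in dog 3 and HAS1, a hyaluronan synthase, 5.96-fold. TMEFF2 and TEX26 were 10.9-fold and 4.31-fold higher in dog 3, and PRG4, the lubricating proteoglycan lubricin, stood at 9.86 against 6.30 in dog 2. Higher in dog 2 were FGL1, a secreted fibrinogen-related protein (9.97 ± 0.12 against 5.89 ± 0.0057, SD, n = 2, limma, adjusted p = 0.00114), GRIA1, a glutamate receptor subunit (9.06 against 5.71), FREM1, a basement membrane protein (7.87 against 5.21), and GJA5, the gap junction protein of arterial endothelium (8.94 against 6.70). OR5BA1 (7.05 against 4.71) and RERGL (5.06 against 2.99) were also higher in dog 2. Levels are given in place of folds where the lower one lay below the medians of the SVF arrays (6.80 to 6.85), because signal over background was not measured, and the dog 3 levels of OR5BA1 and RERGL lay below the lower quartiles of those arrays (4.98 and 4.96). A second feature of GRIA1 gave a smaller difference, 1.40 against 3.35 log2 units. In total 414 features passed, 184 higher and 230 lower in dog 2. Among them were 275 genes (149 higher and 126 lower), 269 of them by at least 2-fold. The feature count also depended on the settings. It was 741 with a filter on dim features and 652 with the replicate number as a term, the latter chosen after the data were seen. The balance turned with repeated quantile normalization, to 222 higher and 211 lower over the 8 arrays and 253 and 230 over all 11, and with single-gene features, a setting chosen after the data were seen, to 335 and 285. The count rests on the 4 SVF arrays: without 1 of them it was 13 (dog 2 replicate 1), 9 (dog 2 replicate 2), 6 (dog 3 replicate 1) or 19 (dog 3 replicate 2), and without either dog 2 PRP array it was 151. Of the named genes, SFRP4, FGL1 and PI3 passed in each of the 8 fits without 1 array. The calls of GJA5, TEX26, OR5BA1 and RERGL were lost without any 1 of the 4 SVF arrays, with adjusted p up to 0.0950, 0.0901, 0.0729 and 0.0950. GRIA1 was lost without either dog 2 SVF array or dog 3 SVF replicate 1 (adjusted p = 0.0606, 0.0981 and 0.0729), and FREM1 (0.0570 and 0.0729) and TMEFF2 (0.0527 and 0.0729) without dog 2 SVF replicate 2 or dog 3 SVF replicate 1. HAS1 (0.0729) and PRG4 (0.0589) were lost without dog 3 SVF replicate 1.

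Marker transcripts of several cell types differed between the dogs in the same arrays, with 1 animal on each side. Endothelial markers were higher in dog 2 in 19 of 21 members (median 1.30, camera, adjusted p = 2.9e-19, and adjusted p = 0.149 with an estimated correlation). Of these, 18 were higher adjusted over the list alone and 8 over all genes, among them VWF (3.86-fold), KDR, the main VEGF receptor (3.09-fold), and FLT1 (2.85-fold). Pericyte and smooth muscle markers were higher in 15 of 16 (median 1.03, adjusted p = 1.5e-13, and adjusted p = 0.144 with an estimated correlation), with 12 past adjusted over the list alone and 4 over all genes, and MYH11, smooth muscle myosin, stood at 8.43 in dog 2 and 6.08 in dog 3. Adipocyte markers (median 0.81, adjusted p = 2.2e-10, and adjusted p = 0.316 with an estimated correlation) and mast cell markers (median 0.77, adjusted p = 5.7e-07, and adjusted p = 0.149 with an estimated correlation) were higher in dog 2 as well. NF-kappaB targets were lower in dog 2 in 18 of 19 members (median -1.12, adjusted p = 1.1e-15), and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.0246). BIRC3, an inhibitor of apoptosis, was 4.22-fold and MAP3K8 2.93-fold higher in dog 3, and 16 members were lower in dog 2 adjusted over the list alone, 4 over all genes. Inflammatory cytokines and chemokines were lower in dog 2 in 24 of 25 (median -0.82, adjusted p = 3.6e-08, and adjusted p = 0.155 with an estimated correlation), with the interferon-induced chemokine CXCL10 at 6.04 in dog 2 and 8.81 in dog 3. Of 21 stromal markers 17 were lower in dog 2 (median -0.37, adjusted p = 0.000126, and adjusted p = 0.347 with an estimated correlation), including NT5E (CD73), 8.48-fold higher in dog 3, and PI16, 3.50-fold. Also lower in dog 2 were matrix proteases and inhibitors (median -0.66, adjusted p = 5.5e-05, and adjusted p = 0.144 with an estimated correlation), extracellular matrix (-0.32, 0.000154, and adjusted p = 0.466), immediate early genes (-0.31, 0.000624, and adjusted p = 0.513), macrophage and monocyte markers (-0.51, 0.00174, and adjusted p = 0.709) and cell cycle genes (-0.30, 0.00641, and adjusted p = 0.709). Altogether 12 of 30 lists passed, 4 higher and 8 lower in dog 2. Each of the 9 genes named here lost its call over all features without any 1 of the 4 SVF arrays, with adjusted p up to 0.0738 (CXCL10), 0.113 (NT5E), 0.114 (PI16), 0.132 (KDR, FLT1, MAP3K8 and MYH11), 0.137 (VWF) and 0.183 (BIRC3). Without both number 2 PRP arrays those of MYH11 (0.0518), KDR (0.0582), MAP3K8 (0.0592) and FLT1 (0.0623) were lost too.

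The 3 companies received equal portions of fat from 1 dog, and the comparison asks how alike their products were. No test is possible with 1 array each, and company cannot be told apart from the chance of 1 preparation. Company B stood apart. Between A and B 1610 genes (10.1%) differed at least 2-fold and between B and C 1552 (9.73%), against 261 (1.64%) between A and C. The 4 replicate pairs of dogs 2 and 3, normalized separately, differed in 222, 293, 177 and 755 genes. These counts are not comparable with those of the companies, since A and C had identical values in 7341 genes, A and B in 6345 and B and C in 6281, against 1 to 4 in the replicate pairs. Of the genes that differed between A and B, 890 were higher in A and 720 in B, a split that became 745 and 1030 when each array was centred on its median.

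The company B array had high levels of proliferation and sterol genes and low levels of immune and endothelial genes. Against the mean of the other companies, 21 of 26 cell cycle genes were at least 2-fold higher (median 1.81, random lists -0.011 to 0.16) and 16 of 17 cholesterol synthesis genes (median 1.99, random lists -0.099 to 0.26). SQLE stood at 10.94 in B against 7.28 in A and 7.12 in C, and CDK1, the kinase that drives mitosis, at 7.47 against 4.58 and 5.13. UCHL1, a ubiquitin hydrolase, stood at 10.05 against 4.91 in A and 5.18 in C, and CDH2, N-cadherin, at 9.42 against 5.39 and 5.15. FABP3, a fatty acid binding protein, was 22.0-fold and ASNS, asparagine synthetase, 13.1-fold above the nearer of the other companies, and ANLN, a cytokinesis protein, stood at 9.69 against 6.10 in A and 6.07 in C. Inflammatory cytokines and chemokines had a median of -2.60, with 17 of 25 at least 2-fold lower (random lists -0.028 to 0.13), macrophage and monocyte markers -2.24 with 16 of 22, NF-kappaB targets -2.02 with 14 of 19, immediate early genes -1.69 with 18 of 24 and endothelial markers -0.76 with 9 of 21. PECAM1, an endothelial and leukocyte adhesion molecule, stood at 3.99 in B against 8.62 in A and 9.18 in C, and LYZ, lysozyme, at 4.77 against 9.88 and 10.46. Lower in B than in both others were PDK4 (3.58 against 10.89 in A and 10.72 in C), FGL1 (3.72 against 10.92 and 10.70), PI3 (5.59 against 12.38 and 12.60), CXCL8 (5.58 against 12.28 and 12.59), DLA-DQA1, a class II histocompatibility gene (4.85 against 11.28 and 11.34), and PRG4 (4.38 against 10.49 and 10.56). The lower quartile of the B array was 3.57 and its median 5.14, PI3 and CXCL8 lay above that median, and signal over background was not measured, so levels are given for these 6.

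The company C array had the highest levels of platelet and early response genes. PPBP stood at 11.14 in C against 5.62 in A and 5.08 in B, and the platelet list had a median of 1.36, with 8 of 13 members at least 2-fold above the mean of the others (random lists -0.092 to 0.065). NRGN, 7.89 against 4.63 and 5.06, and TUBB1, 6.40 against 4.14 and 4.36, were among them. Inflammatory cytokines and chemokines (median 2.00, 16 of 25 at least 2-fold higher), immediate early genes (1.66, 21 of 24) and heat shock genes (0.91, 5 of 15) were higher in C than the mean of A and B, with IL6 at 10.50 against 7.84 in A and 3.77 in B. Much of this size came from B: the mean level of the inflammatory list was 8.47 in C, 7.91 in A and 5.54 in B, and that of immediate early genes 10.21, 9.24 and 7.80. CXCL8 stood at 12.59 in C and 12.28 in A. RGS4 (7.59 against 4.78 and 4.06), RRAD (7.50 against 5.05 and 4.15) and GPRC5A (9.99 against 7.61 and 6.97) also lay above both others, and CEP55, C10H12orf66, ZMAT3, CHEK2, TAS2R40 and ECT2 lay below both, by between 1.19 and 1.47 log2 units to the nearer. In company A, the red cell genes ALAS2 (4.33-fold) and HEMGN (3.59-fold) and MIOX, ATP8B4, TENT5C and FRMD4B lay above both others, while TNFRSF12A (3.53-fold), AP4S1, HMOX1 (haem oxygenase 1, 3.16-fold), CRYAB, MIF and ID1 lay below both. Outside the central range of random lists were 9 lists higher and 8 lower in A, 5 and 15 in B, and 16 and 4 in C. The mean that A and C were each set against held B, so a departure of B alone puts lists of A and C outside the range in the opposite direction, and the 3 counts are not independent. In addition, 9540 features (29.5%) had one identical value on all 3 arrays, which narrows the random ranges.

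**Figure D4:**
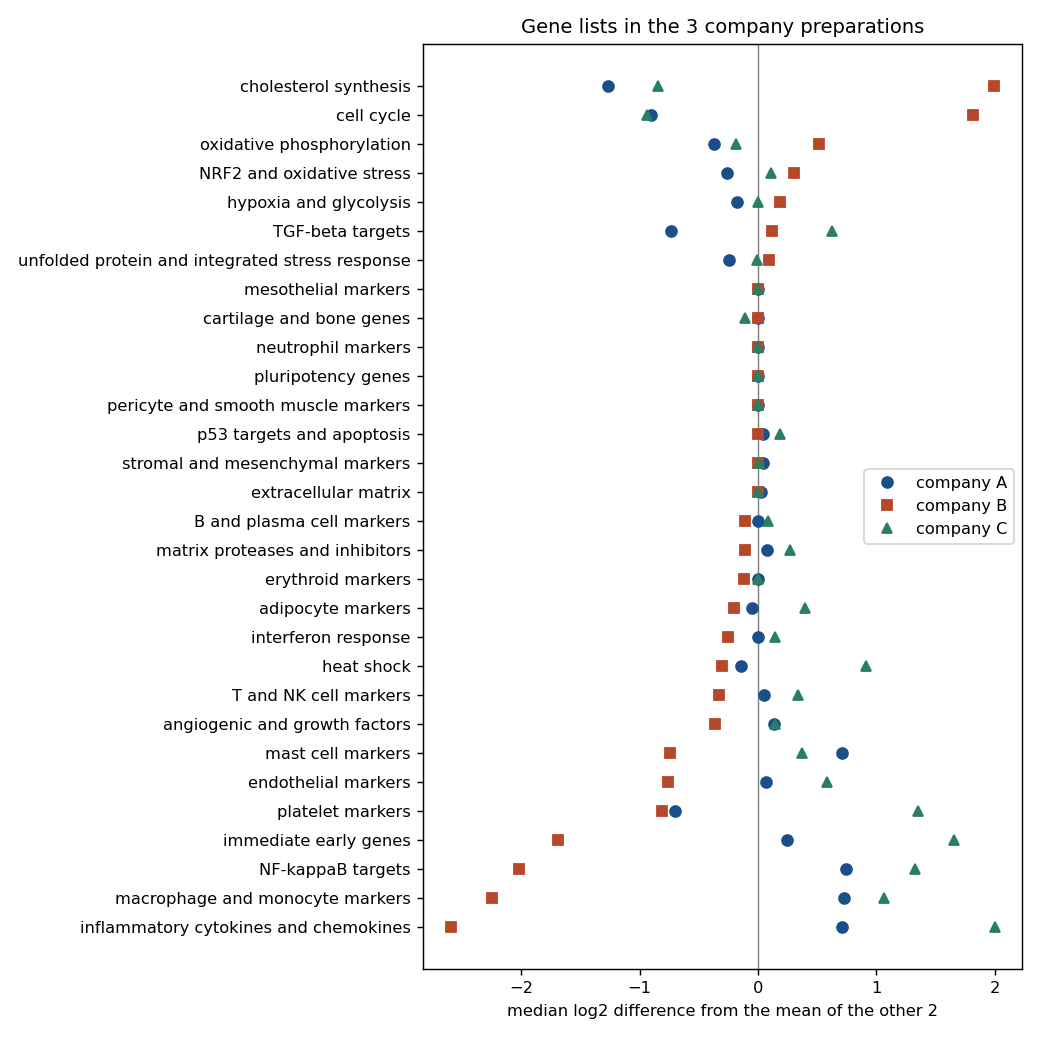
Median log2 difference of the members of each of 30 gene lists from the mean of the other companies, for company A (circles), B (squares) and C (triangles), 1 array each. Company B lies at 1.99 for cholesterol synthesis and -2.60 for inflammatory cytokines and chemokines, and company C at 1.36 for platelet markers.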

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

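Of the tests in this part, the split of PPBP by pair number and the tests on the number 2 pairs were chosen after the result was seen. In 7 gene lists the response to PRP with incubation differed between the dogs in camera's test of the difference (dog 3 minus dog 2), and none of these calls held with an estimated correlation. The median differences were -0.43 for adipocyte markers (adjusted p = 4.6e-05; adjusted p = 0.828 with an estimated correlation), -0.38 for NF-kappaB targets (0.000229; 0.280), -0.28 for endothelial markers (0.00141; 0.828), -0.34 for mast cell markers (0.00141; 0.828), -0.26 for immediate early genes, -0.31 for cell cycle genes and 0.18 for NRF2 genes (0.0209 for each of these 3; 0.828). Adipocyte markers had a median of -0.32 in dog 2 and -0.72 in dog 3. The gap lay mainly in the number 2 pairs (-0.18 and -0.85, against -0.45 and -0.57 in the number 1 pairs), which hold the dog 3 PRP replicate 2 array. Both dogs moved between the numbers: the members' mean for number 2 minus number 1 was 0.35 in dog 2 and -0.22 in dog 3. MMP8, a neutrophil collagenase, differed by -0.085 in dog 2 and 0.45 in dog 3, with both PRP arrays below both SVF arrays in dog 2 and above them in dog 3; the difference of 0.53 was not past the threshold, since no feature was.

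The rise of PPBP could come from platelet RNA carried by the PRP, from leukocytes in it, or from inflammatory activation of the cells. The 6 other platelet list members taken for this test had a median difference of 0.083 and a mean of 0.071 ± 0.061 (SE over genes), against 2.71 for PPBP. Of these, ITGB3 already stood at 9.41 and 10.81 in the untreated SVF of dogs 2 and 3. The bound set beforehand for platelet RNA, a median above 0 by 2 standard errors, was not met. The criterion set against it had 2 parts. The part on the mean plus 2 standard errors (0.19) was met, and a median at or below 0 was not. By these bounds that source stays open. Neutrophil markers, the only leukocyte list taken for this test, did not pass (camera, adjusted p = 0.0807). Their median was above 0, which leaves leukocytes open. T and NK cell, B and plasma cell and macrophage lists were higher with the preset correlation but not with an estimated one. The SVF holds immune cells itself, so these lists cannot tell its own cells from those of the PRP. The inflammatory list met the criterion written for activation (adjusted p = 2.8e-08), but the call was lost with an estimated correlation (0.357), so it is read as undecided. The PPBP rise was 0.38 ± 0.007 larger (SE over 2 dogs) in the number 2 pairs, where the inflammatory members' mean difference was 0.86 larger. This value meets both the criterion for activation and the one against it, so the criteria decide nothing. In dogs 2 and 3 PPBP rose by 3.07 and 1.98 in the number 1 pairs and by 3.45 and 2.35 in the number 2 pairs. The inflammatory list's medians were 0.50 and 0.13 in the number 1 pairs and 0.85 and 0.92 in the number 2 pairs. In the number 1 pair of dog 3, a single pair, PPBP thus rose where the list moved little.

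The lower adipocyte markers could reflect dilution of SVF RNA by RNA from another source. Dilution would lower markers of all SVF cells alike. The adipocyte mean (-0.58, 20 genes) lay below that of stromal and endothelial markers (-0.085, 42 genes) by a difference of -0.49 ± 0.10 (SE over genes). This met the bound set against dilution as the whole cause. The pooled mean joins a stromal mean of 0.029 and an endothelial mean of -0.20. The SE treats genes as independent, while the estimated correlation was 0.444 for adipocyte and 0.379 for endothelial markers, so the argument is weak. Loss of fat cells during incubation and a lower expression within them stay open and were not tested.

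Inflammatory genes differed more in the number 2 pairs in 18 of 25 members, an observation made in these data and then tested on them (camera, adjusted p = 0.000444, and adjusted p = 0.787 with an estimated correlation; in limma 0 members passed), so the pattern itself is uncertain. In dog 2 alone the members' mean was 0.60 ± 0.23 (SE over genes) higher. This met the bound set against the dog 3 PRP replicate 2 array as the only source. In dog 2 a single pair is set against another, so the SE does not measure the spread between arrays and the question is not settled. The median of all genes moved by 0.013 where the list's median moved by 0.69, which met the bound set against array scaling. The medians of the 8 arrays already lay close together (6.76 to 6.85), so that median was bound to move little. The test therefore cannot decide about scaling. The macrophage mean differed from the inflammatory mean by -0.61 ± 0.25 (SE over genes). This met the bound set against a higher share of macrophage RNA as the whole cause. The SE treats genes as independent, while the estimated correlation within the macrophage list was 0.733, so that test is weak. The list's mean level was lower on the number 2 than on the number 1 PRP arrays (9.30 against 10.07 in dog 2, 9.86 against 10.04 in dog 3). These levels give no sign of a higher share than on the number 1 PRP arrays. The number 2 SVF arrays were lower too (8.82 against 9.75 and 9.53 against 10.05). A larger rise in this share over the same-numbered SVF stays open. A difference in handling between the samples numbered 1 and 2 may be the source and is open, because the labels do not say what the numbers stand for.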

How the results depend on the processing

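The settings that use 1-gene features, distinct features, the replicate number as a term, no number 2 PRP arrays, or other column orders in fry were chosen after seeing the data. The main count of 2 features was 1, the higher one (PPBP), with the filter on dim features, single-gene features or the number term. It was 1, a lower one and not PPBP, with the additive model, condition alone or the random dog block, all of which ended the PPBP call. It was 0 with the replicate block (4 pairs), 1 mean per dog and condition, without both number 2 PRP arrays, and without any single array (0 to 0); fewer arrays leave fewer degrees of freedom, and otherwise the cause was not tested. The difference of PPBP stayed above 0 in all 23 settings; its adjusted p ranged from 0.00251 to 0.439 and it was past the threshold in 9. Dog 2 alone gave 1 feature with the filter, single-gene features or the number term. Dog 2 against dog 3 gave 741 features with the filter, 652 with the number term, 85 without both number 2 PRP arrays and 6 to 385 without single arrays. The correlation between dogs was 0.735 with the filter and 0.364 to 0.634 without single arrays. With an estimated correlation 0 lists passed and with fry 2. The filter left 13 lists and repeated quantile normalization 12, over 8 or 11 arrays; lists were not tested with the random dog block. Fry's count was 3 or 0 when the columns of the design were put in another order, so no statement rests on it. Immediate early genes turned in camera's direction without both number 2 PRP arrays, at a median of -0.035 (adjusted p = 0.889). Without single arrays 10 to 16 lists passed. Adipocyte, inflammatory, T and NK cell, pericyte and NRF2 lists passed in all 8 of these fits. Single arrays ended the calls for cell cycle (dog 2 PRP 1, dog 2 SVF 2, dog 3 PRP 1, dog 3 SVF 2), immediate early genes (the SVF 2 and PRP 2 arrays of both dogs), oxidative phosphorylation (dog 2 SVF 1, dog 3 PRP 1, dog 3 SVF 2), the unfolded protein response (dog 2 SVF 1, dog 3 SVF 1, dog 3 PRP 2), extracellular matrix (dog 2 SVF 1), endothelial markers (dog 3 PRP 2), macrophages (dog 2 PRP 1, dog 2 SVF 2, dog 3 PRP 1), B and plasma cells (dog 3 SVF 1, dog 3 PRP 1), platelet markers (dog 2 SVF 1, dog 3 SVF 1, dog 3 PRP 1) and mast cells (dog 2 SVF 1, dog 2 PRP 1, dog 3 SVF 1, dog 3 PRP 1). Among the calls over all features and of lists in the main comparison, the replicate block ended those of PPBP, the unnamed feature, platelet markers and mast cell markers and no other. Calls adjusted over a list alone and list calls on the difference between the dogs' effects were not repeated with the block. The list tests between the dogs were not repeated without single arrays. At 3-fold the companies differed in 697 (A and B), 58 (A and C) and 767 (B and C) genes, a stricter bound by construction. Signal over background was not measured.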

Other observations

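The tests in this part on pair number were chosen after the result was seen; the count of splits was planned. Other gene groups also differed between the number 2 and the number 1 pairs. The difference between PRP and SVF was higher in the number 2 pairs by 0.92 ± 0.25 log2 units for NRF2 genes (mean, SE over genes; camera, adjusted p = 5.9e-06), and the number 2 minus number 1 value was -0.40 ± 0.11 for endothelial markers (5.5e-05) and -0.40 ± 0.078 for immediate early genes (3.7e-06). With an estimated correlation the adjusted p was 0.787 for each of these lists, and in limma no member of them passed. CCL7, a monocyte chemokine, differed by 3.90 between PRP and SVF in the number 2 pair of dog 2 and by 0.51 in its number 1 pair, and by 2.94 and -0.034 in dog 3. In limma with a number by condition term (3 residual degrees of freedom), 2 features passed: CYP1A1, a target of the aryl hydrocarbon receptor (4.07, adjusted p = 0.0427), and an unnamed feature; 7 lists passed with the preset correlation and 0 with an estimated one.

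Among the 35 splits of the 8 arrays into 4 and 4, fitted without other terms, 3 gave at least 1 feature, the real split, which gave 1, included, so chance is not excluded. The fit of the real split is the one with condition alone, without the dog. Its feature was a lower one and not PPBP (limma, adjusted p of PPBP = 0.345), so the splits do not test the PPBP rise. Of the other splits, 1 gave 6 features, and the split by dog gave the highest count, 2034. That split parts the animals together with their tissue and preparation, which cannot be told apart. Of the 8 splits that part all 4 pairs, the highest other count was 0, and 8 splits are too few for a share under 0.05.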
